A study of Homo sapiens with 2 samples.

How the data were processed

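The samples were 1 untreated culture and 1 culture treated with ACBP-S-Se of the gastric cancer cell line MKN-45, each measured once. Per the labels' protocols, total RNA with a passing integrity number was depleted of ribosomal RNA with a Ribo-Zero kit and made into stranded libraries. HISAT2 and StringTie are named in the submitters' processing notes, without versions. The genome build and annotation release are not given in the sources used here.

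The authors deposited a table of 135995 isoforms with an FPKM column and a coverage column per library, per the file headers. Isoforms carry Ensembl identifiers (119780) or assembled names (16215, 11.9%), with gene names as deposited. No isoform was at 0 in both libraries. The deposited coverage divided by the deposited FPKM gave a single constant per library, 8.698 for untreated and 10.1 for ACBP-S-Se, which by the definition of FPKM is the number of aligned gigabases. The isoforms in the table accounted for 72.96% and 75.1% of those bases. Read length is not given in the sources used here, so reads per gene and counting intervals were not computed. The higher number of isoforms above 0 in the ACBP-S-Se library goes with its larger number of bases.

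Coordinates are those of the file. Of 11151 protein-coding genes matched by symbol to the RefSeq table of GRCh38.p14, 11148 overlapped their position there, so the coordinates are read as GRCh38. That table also gave the biotypes, by symbol or synonym. Of the 13965 genes tested, 1352 had no match.

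The value of a gene was the sum of FPKM over isoforms that share its name. Genes with a mean FPKM of at least 1 over both libraries were compared with a fold of 2, on log2((ACBP-S-Se + 1)/(untreated + 1)). With 1 library per group no test was run, and the limma fit that had been set for replicated columns was not made. The 30 gene lists were fixed before the data were examined, as were the rule for named genes and 8 of the alternatives. For each list with at least 5 tested members, a minimum set after the data were seen, the median log2 ratio was placed among 10000 random lists of the same size, drawn with replacement from the same 10 bins of mean expression. A list was said to stand apart outside the central 95% of the random medians. Lists covered the stress programmes and selenium biology of the treatment, cell cycle, metabolism, epithelial identity, noncoding RNAs and markers of other cell types. One list is named here by 3 of its members, CDKN1A, MDM2 and BBC3. The values of a few genes are not reported here. A second matching added 5 bins of transcript length, taken as the mean isoform length weighted by FPKM.

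Named genes were the 15 coding genes with the highest and the 15 with the lowest ratio among those with a mean FPKM of at least 5 and a value above 0 in both libraries, and the 5 highest and 5 lowest long noncoding RNAs with a mean of at least 1. Small RNAs, mitochondrial rRNA and tRNA and clone-named loci were left out of the 15. From each list that stood apart, up to 6 members with the largest change in its direction were named under the same limits, from each oxidative stress list the 2 members with the largest change each way, and lastly the 5 genes listed at 0 in 1 library with the highest value in the other.

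The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5, centring on the median, trimmed-mean scaling (30% of log ratios and 5% of levels), rescaling without small RNAs and mitochondrial genes, the highest isoform of each gene, and annotated isoforms alone. Added after the data were seen were aligned bases, scaled by depth, over all transcripts of a gene's assembled locus (pseudocount 2), a gene level without intronic, antisense and flanking assembled transcripts, length matching, and leaving out genes listed at 0 in 1 library. A gene's name is shared by transcripts that overlap its neighbours, and short-read assembly divides bases between overlapping isoforms, so isoform values carry an error that FPKM does not show.

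Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. On simulated values for 13965 genes of this comparison, 100% of 100 genes raised 8-fold and 100% of 100 genes lowered 8-fold passed a fold of 2, 0.705% of unchanged genes did, and 5.5% of 200 unchanged lists fell outside the bounds. The simulated noise had a chosen size and was independent between genes, without isoform assignment error or a length trend. These shares therefore check the calculation only and give no rate of false calls for these libraries.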

Results

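MKN-45 is an established human gastric cancer cell line. One culture was left untreated and another was treated with ACBP-S-Se, a bioactive polypeptide that chelates selenium, and the study's stated subject is oxidative stress under this treatment. Total RNA depleted of ribosomal RNA was sequenced, with 1 library per group, and the labels give no dose or duration. Expression is given as FPKM (fragments per kilobase of transcript, scaled by the fragments mapped in the library) for 135995 isoforms, of which 111235 had a value above 0 in the untreated library and 120412 in the ACBP-S-Se library. By the ratio of coverage to FPKM, 8.698 gigabases were aligned in the untreated library and 10.1 gigabases in the ACBP-S-Se library. Because each group is a single library, no difference below has a replicate check, no p-value or standard deviation can be given, and higher and lower describe this pair of libraries. Ratios are log2((ACBP-S-Se FPKM + 1)/(untreated FPKM + 1)), and folds are on that scale, which understates the change of genes with low values.

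The comparison of ACBP-S-Se with untreated cells asks which transcripts differ after the treatment. CDKN1A, which encodes the cell cycle inhibitor p21, had the highest ratio among coding genes with a mean FPKM of at least 5 and a value above 0 in both libraries, at 14.5 FPKM in untreated and 387 in ACBP-S-Se cells, a fold of 25.02 (chromosome 6, 36676460 to 36687339, plus strand). Gene lists of the gastric and intestinal epithelium, DNA replication, mitosis and antioxidant enzymes had medians below those of most random lists, although in the last 3 most members stayed within a fold of 2. A list that includes CDKN1A, MDM2 and BBC3 and a list of hypoxia and glycolysis genes had medians above them. KEGG pathways named in the deposited table, examined after the lists had been seen, lay within the bounds on some of the same themes, as given below. Of 13965 named genes with a mean FPKM of at least 1, 1804 (12.9%) were at least 2-fold higher and 1635 (11.7%) at least 2-fold lower. The median log2 ratio over these genes was 0.055, with quartiles of -0.50 and 0.59. Among 11622 genes that RefSeq lists as protein-coding, 1408 were higher and 1307 lower by that measure. With a mean FPKM of at least 5 required, the counts were 1095 higher and 957 lower, as fewer genes were tested.

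Gene lists fixed in advance were described by the median log2 ratio of their members and by its percentile among 10000 random lists matched on mean expression. Of 27 lists with at least 5 members tested, 4 lay above the central 95% of random lists and 6 below it. Lists of independently drawn genes would place about 1.35 outside these bounds. Members of a list can vary together and some lists share genes, so more could lie outside without an effect of the treatment. With 1 library per group that number is unknown. A percentile of 0 or 100 means that no random list reached the value. Pairs of values joined by "to" in parentheses are the FPKM in untreated and then in ACBP-S-Se cells.

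**Figure D1:**
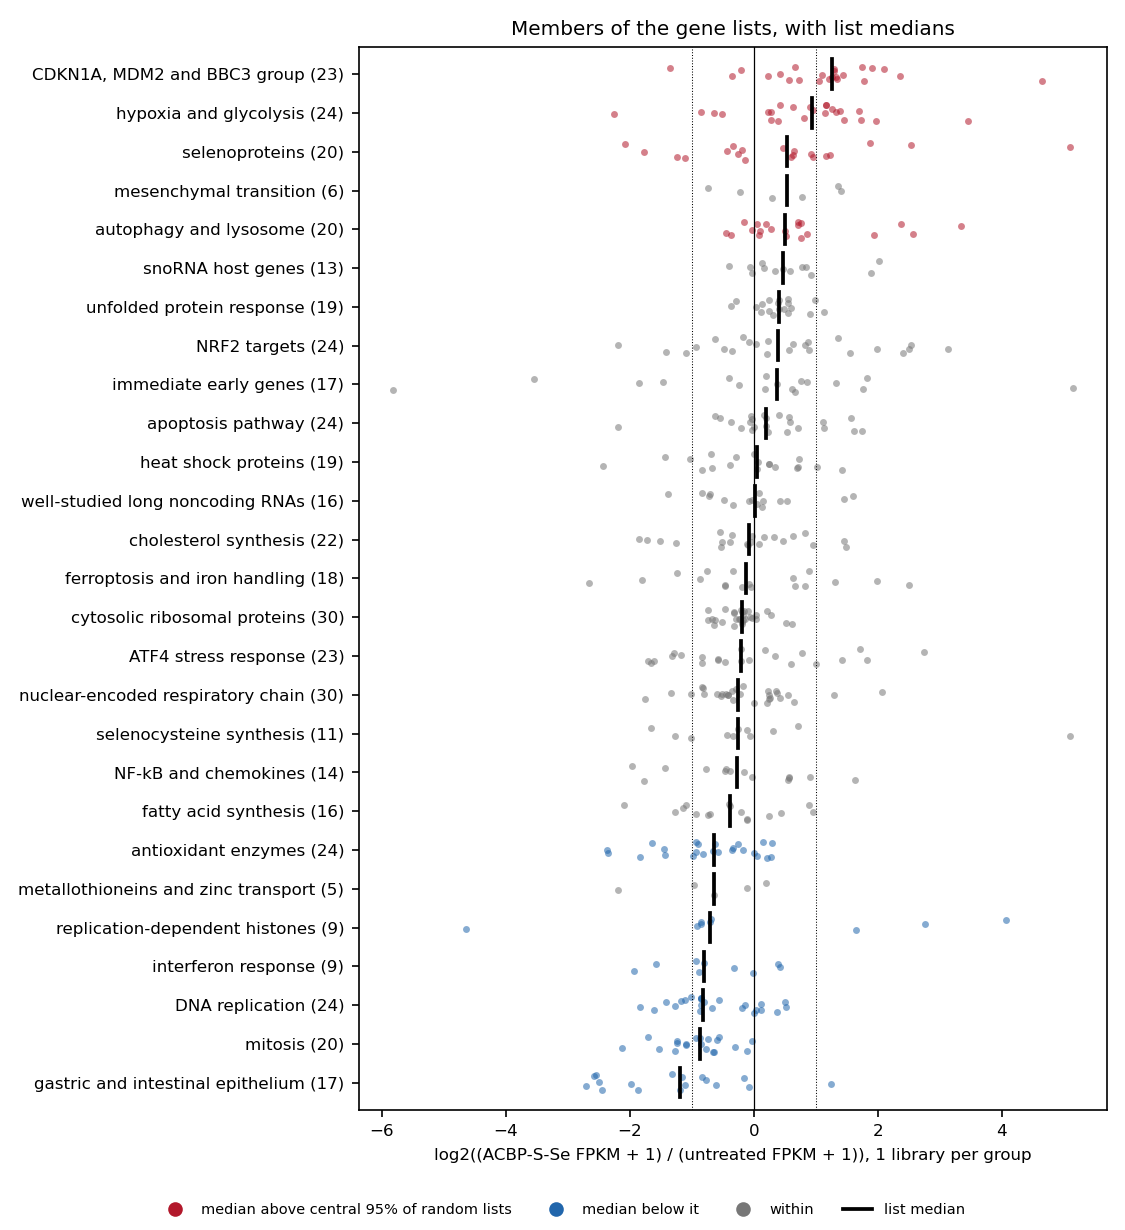
Each point is a tested member of a gene list, placed by its log2 ratio of ACBP-S-Se over untreated FPKM (pseudocount 1, x axis), with 1 library per group; the number tested stands after each list name, black bars are list medians and dotted lines mark a fold of 2. Among the lists shown, those with a percentile, the CDKN1A, MDM2 and BBC3 group has the highest median, 1.26, and the gastric and intestinal epithelium list the lowest, -1.20.

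The list named here by 3 members, the CDKN1A, MDM2 and BBC3 group, had the highest median of the lists with a percentile. Its median log2 ratio was 1.26 (percentile 100), and 15 of 23 tested members were at least 2-fold higher against 1 lower. Among members with a mean FPKM of at least 5, the highest ratios after CDKN1A were those of PLK2, a stress-responsive kinase (5.88 to 34.1 FPKM), and TIGAR, a regulator of glycolysis and redox balance (5.15 to 25.4). Under the same limit, next came the nuclease AEN (26.2 to 92.5), BBC3, which encodes the pro-apoptotic protein PUMA (7.37 to 26.9), and the DNA damage sensor XPC (7.34 to 21.7). A KEGG pathway of 62 genes that shares members with this list had a median of 0.20 and lay within the bounds (percentile 86.2, 79.9 with length matching). Of its genes, 19 were at least 2-fold higher and 6 lower. The hypoxia and glycolysis list had a median of 0.93 (percentile 100), with 11 of 24 members at least 2-fold higher and 1 lower. Its leading members were the glycolytic enzyme PGAM1, at 26.6 FPKM in untreated and 300.2 in ACBP-S-Se cells, the histone demethylase KDM3A (52.7 to 210.0), the stress-responsive gene NDRG1 (265 to 879.7), the hexokinase HK2 (53.1 to 175), the collagen prolyl hydroxylase subunit P4HA1 (56.5 to 156) and the mitophagy receptor BNIP3 (83.02 to 219). The KEGG pathways of glycolysis and gluconeogenesis (median log2 ratio -0.012 over 48 genes, percentile 31.7, 23.1 with length matching) and HIF-1 signaling (median log2 ratio 0.22 over 76 genes, percentile 91.1, 79.8 with length matching) lay within the bounds. In the glycolysis and gluconeogenesis pathway 10 genes were at least 2-fold higher and 7 lower, and in HIF-1 signaling 16 were higher and 9 lower. The list and these pathways were not compared with each other. Autophagy and lysosome genes had a median of 0.51 (percentile 98.3), 4 of 20 being at least 2-fold higher and 0 lower. MAP1LC3B, which encodes the autophagosome protein LC3B, stood at 5.71 and 66.9 FPKM, GABARAPL1 at 2.9 and 19.2, and the autophagy receptor SQSTM1 at 133 and 513. The SQSTM1 difference lay in assembled isoforms, since its annotated isoforms alone gave a log2 ratio of -2.01, and the autophagy list came within the bounds when only annotated isoforms were summed (percentile 93.8), when a mean FPKM of 5 was required (96.96) or when each gene was read from its highest isoform (97.1). The KEGG pathway of animal autophagy lay above the bounds (median log2 ratio 0.49 over 117 genes, percentile 100, 100 with length matching) and that of the lysosome within them (median log2 ratio 0.026 over 108 genes, percentile 33.98, 32.5 with length matching).

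The lists of DNA replication and mitosis had low medians. For DNA replication the median was -0.83 (percentile 0), with 7 of 24 members at least 2-fold lower and 0 higher. RRM2, a subunit of ribonucleotide reductase, was at 29.2 FPKM in untreated and 7.49 in ACBP-S-Se cells, the DNA ligase LIG1 at 10.4 and 3.26, and the replicative helicase subunit MCM5 at 17.05 and 6.49. The mitosis list had a median of -0.86 (percentile 0), 8 of 20 members being at least 2-fold lower and 0 higher, among them the cyclin CCNA2 (15.4 to 2.75 FPKM), the kinases PLK1 (53.6 to 15.7) and AURKB (15.7 to 4.801), the cyclins CCNB1 (31.8 to 12.6) and CCNB2 (38.03 to 15.5) and the topoisomerase TOP2A (50.5 to 20.8). Over its whole locus, CCNA2 had a log2 ratio of -0.51 in place of -2.13. The KEGG pathway of DNA replication was also low (median log2 ratio -0.46 over 35 genes, percentile 0.12, 0.12 with length matching). That of the cell cycle lay within the bounds (median log2 ratio -0.0061 over 114 genes, percentile 21.6, 11.7 with length matching). Replication-dependent histones had a median of -0.71 (percentile 1.83, and 3.38 when random lists were also matched on transcript length). However, 3 of 9 tested members were at least 2-fold higher and 1 lower, and their mean log2 ratio was -0.021. Of the higher members, HIST1H4C and HIST1H4D were listed at 0 in untreated cells, which may be failed estimates, and had locus log2 ratios of 0.55 and 0.93. Single histone genes went both ways, with HIST1H1E at 419 and 15.9 FPKM, HIST1H4E at 249 and 132, and HIST1H4H at 4.401 and 89.7, and their near-identical copies make the value of any one of them uncertain.

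The gastric and intestinal epithelium list had the lowest median of the lists with a percentile, -1.20 (percentile 0.01), and 11 of 17 members were at least 2-fold lower against 1 higher. The simple-epithelium keratins KRT18 (579 FPKM in untreated and 87.8 in ACBP-S-Se cells; chromosome 12, 52948871 to 52952901, plus strand), KRT8 (463 to 81.3) and KRT19 (176 to 31.4) were lower by folds of 6.54, 5.64 and 5.47. The carcinoembryonic antigen genes CEACAM6 (507 to 86.5) and CEACAM5 (328 to 82.1) and the brush border gene VIL1 (10.97 to 2.26) were also lower. KRT8 kept a log2 ratio of only -0.63 in annotated isoforms, against -2.49 over all its isoforms. MET, the receptor kinase gene for which this cell line is known to carry extra copies, was at 517 and 339.7 FPKM, and E-cadherin (CDH1) at 118 and 106; these and the higher member, CDX2 (2.62 to 7.603), were chosen after their values were seen. Of 13 listed markers of blood, endothelial and stromal cells, only LYZ (14.5 to 1.403) and ACTA2 (8.92 to 19.5) reached a mean FPKM of 1. The interferon response list had a median of -0.81 over 9 tested members (percentile 0.81), 2 of them at least 2-fold lower and 0 higher. OAS1 stood at 19.3 and 4.299 FPKM and OAS3 at 10.9 and 2.99. OAS3 had a log2 ratio of only -0.44 in annotated isoforms. The list came within the bounds over whole loci (percentile 3.97), in annotated isoforms (8.69) and with the highest isoform (6.17).

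**Figure D2:**
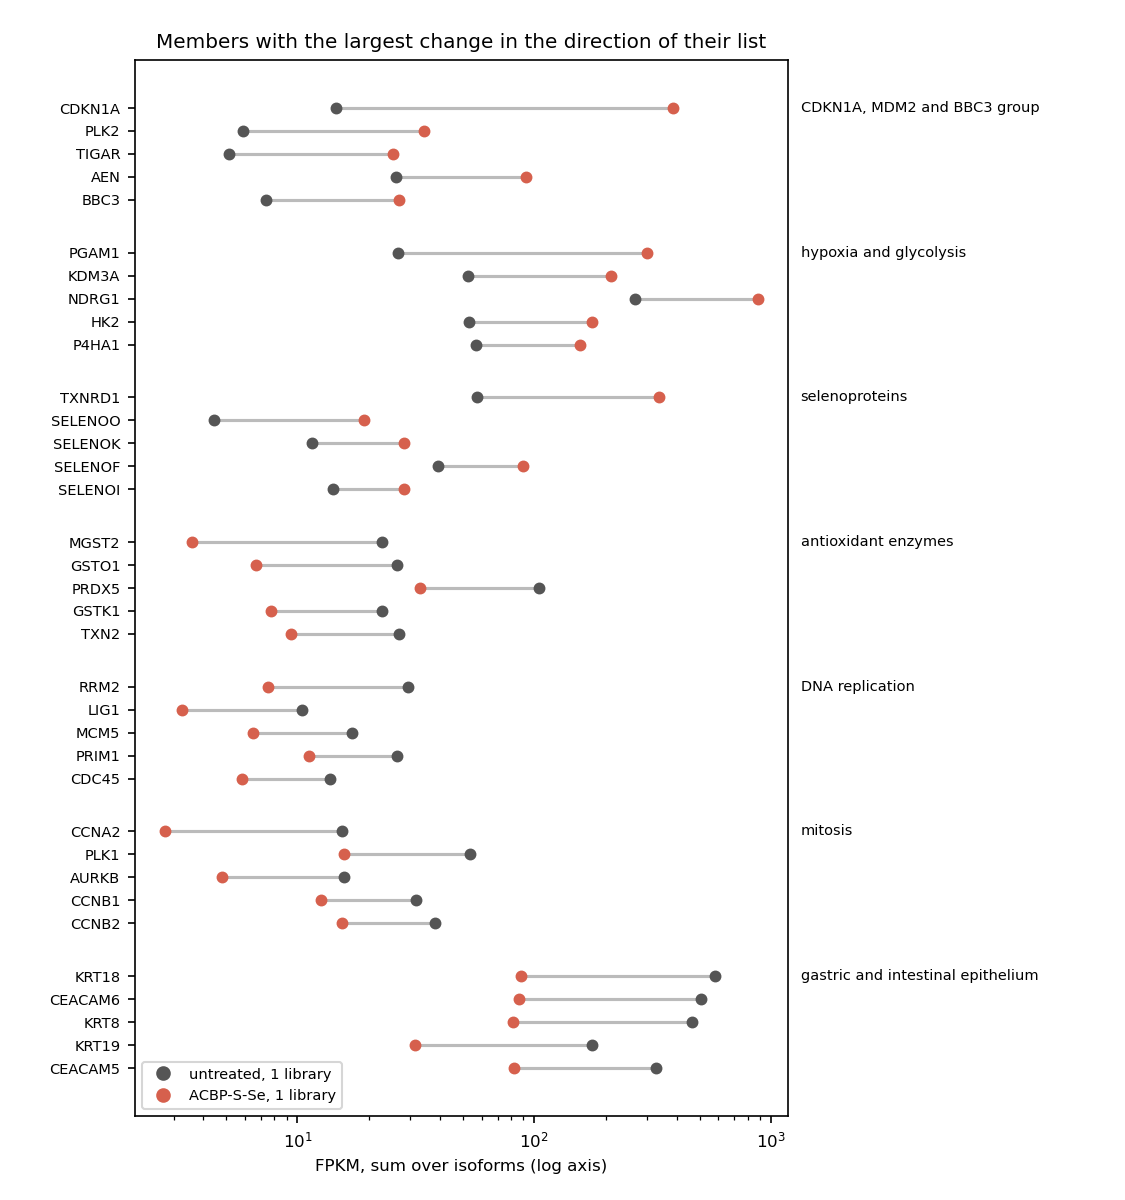
FPKM of named genes in the untreated library (grey) and the ACBP-S-Se library (red) on a log axis, summed over isoforms, for the members with the largest change in the direction of their list; each point is 1 library. CDKN1A lies at 14.5 and 387 FPKM, and KRT18 at 579 and 87.8.

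For the oxidative stress question, the lists divided. The antioxidant enzyme list had a median of -0.64 (percentile 0.02), with 6 of 24 members at least 2-fold lower and 0 higher. The glutathione transferases MGST2 (22.8 FPKM in untreated and 3.602 in ACBP-S-Se cells; chromosome 4, 139665768 to 139740745, plus strand), GSTO1 (26.4 to 6.67) and GSTK1 (22.7 to 7.73) were lower, as were the extracellular superoxide dismutase SOD3 (8.77 to 0.917), the peroxiredoxin PRDX5 (105 to 32.98) and the mitochondrial thioredoxin TXN2 (26.95 to 9.38), although over its whole locus TXN2 had a log2 ratio of -0.056. MGST1 had a ratio of -0.98, but 0.044 in its highest isoform. At the other end of the list, PRDX4 was at 57.8 and 71.4 FPKM and GLRX5 at 18.2 and 22.3. With each gene read from its highest isoform, the antioxidant list lay at percentile 5, within the bounds. The KEGG pathway of glutathione metabolism was low (median log2 ratio -0.67 over 36 genes, percentile 0, 0.02 with length matching). It shares genes with this list, among them MGST2, and 4 of its genes were at least 2-fold higher and 14 lower. The pathways of selenocompound metabolism (median -0.11 over 15 genes, percentile 26.8) and ferroptosis (median -0.082 over 33 genes, percentile 19.985) lay within the bounds.

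Selenoproteins had a median of 0.53 (percentile 98.5), but members went both ways, 5 of 20 being at least 2-fold higher and 4 at least 2-fold lower. The thioredoxin reductase TXNRD1 was at 57.4 FPKM in untreated and 338 in ACBP-S-Se cells, a fold of 5.81 (chromosome 12, 104215779 to 104350305, plus strand), and SELENOO (4.45 to 19.02), SELENOK (11.5 to 28.1) and SELENOF (39.1 to 89.4) were also at least 2-fold higher. However, SELENOO had a log2 ratio of only 0.61 in annotated isoforms. SELENOI (14.1 to 28.2) and SELENOT (18.98 to 37.01) had ratios of 0.95 and 0.93. The glutathione peroxidase GPX2 (46.7 to 10.3) and SELENOW (21.1 to 5.498) had the lowest ratios. SELENOW (locus log2 ratio -0.60) and SELENOH (0.065) were not 2-fold lower over whole loci. The other 2 lower members, GPX2 (locus log2 ratio -1.77) and GPX1 (89.2 to 37.2 FPKM, locus log2 ratio -1.36), were. SEPHS2, counted among the higher members, was listed at 0 in the untreated library and at 33.4 FPKM in ACBP-S-Se cells. That 0 may be a failed estimate, and the gene was chosen for mention after its value was seen. Without genes listed at 0 in a library the selenoprotein list lay at percentile 96.7, over whole loci at 94.8 and with the highest isoform at 71.4, each within the bounds.

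Targets of the oxidative stress factor NRF2 had a median of 0.40, at percentile 95.8 within the bounds, with 7 of 24 members at least 2-fold higher and 3 lower. Beside TXNRD1, the aldo-keto reductase AKR1C2 was higher (1.41 to 20.2 FPKM), while the sulfiredoxin SRXN1 (14.9 to 2.51) and the transporter ABCC3 (32.5 to 11.6) were lower, ABCC3 having a ratio of 0.11 in its highest isoform. The NRF2 list lay above the upper bound in annotated isoforms (percentile 99.8) and with a pseudocount of 0.1 (97.8). It lay further within them with a mean FPKM of at least 5 (percentile 65.8, median 0.12) and over whole loci (percentile 71.4, median 0.23). In the ferroptosis and iron handling list (median -0.13, percentile 21), the ferritin light chain gene FTL was at 157 and 896 FPKM and the heme oxygenase HMOX1 at 0.624 and 5.41, while the iron exporter SLC40A1 (20.1 to 2.32) and the polyamine acetyltransferase SAT1 (309 to 88.1) were lower. The ATF4 stress response list had a median of -0.21 (percentile 9.97). Its members STC2 (27.3 to 189) and ATF3 (14.99 to 55.8) were higher, and CEBPB (24.3 to 6.71) and the cystathionine lyase CTH (75.04 to 23.2) were lower. CEBPB had a log2 ratio of only -0.25 in annotated isoforms. Among 5 tested members of the metallothionein and zinc transport list (median -0.65, percentile 7.75), the zinc exporter SLC30A1 was lower (6.32 to 0.603), MT1X stood at 9.79 and 4.55, MT2A at 3.95 and 4.68, and SLC39A10 at 13.4 and 12.3.

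The remaining lists with a percentile lay within the bounds. Median log2 ratios above 0 were unfolded protein response 0.40 (percentile 93.3), heat shock proteins 0.059 (percentile 46.3), apoptosis pathway 0.20 (percentile 77.01), immediate early genes 0.38 (percentile 91.8), mesenchymal transition 0.53 (percentile 89.8), snoRNA host genes 0.47 (percentile 94.4) and well-studied long noncoding RNAs 0.012 (percentile 43.8). Median log2 ratios below 0 were selenocysteine synthesis -0.26 (percentile 14.7), cholesterol synthesis -0.071 (percentile 24.5), fatty acid synthesis -0.39 (percentile 2.6), nuclear-encoded respiratory chain -0.26 (percentile 2.94), cytosolic ribosomal proteins -0.19 (percentile 10.2) and NF-kB and chemokines -0.27 (percentile 9.78). With a mean FPKM of at least 5 the NF-kB and chemokine list had a median above 0 (0.55, percentile 94.4). The medians of heat shock proteins and well-studied long noncoding RNAs, near 0, also changed sign in some alternatives, the former to -0.26 over whole loci and the latter to -0.33 with a mean of at least 5. With length matching, the snoRNA host genes lay above the upper bound (percentile 99.3) and the fatty acid synthesis genes below the lower (percentile 1.2). The other lists had too few tested members for a percentile. Of 13 mitochondrially encoded proteins, only 6 were listed in the deposited data and 4 were tested, 1 at least 2-fold higher and 2 lower. Among them MT-CYB was at 335 and 21.8 FPKM, while MT-ND6 was listed at 0, which may be a failed estimate, and at 31.4. With most of these genes missing, such values give no reading of mitochondrial expression. The structural RNAs TERC (480.0 to 4.03) and RNU4-1 (747 to 80.02) were lower, and all of these were named after their values were seen.

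Among single coding genes with a mean FPKM of at least 5, the 15 highest ratios included, after CDKN1A, the small GTPase RHOB (3.75 to 76.1 FPKM; chromosome 2, 20447074 to 20450438, plus strand), CHMP1B (0.327 to 20.4), DNAH17 (0.213 to 17.8), PLD6 (0.105 to 15.4), NXT1 (1.17 to 27.5), the Polycomb protein gene CBX6 (1.54 to 30.2), DPM3 (0.437 to 16.3) and ZNF554 (0.677 to 17.8), together with HOXB7, with 12.3 FPKM in ACBP-S-Se cells and a value close to 0 in untreated cells, and the histones HIST2H4B (1.48 to 45.8), HIST2H2AA4 (28.2 to 528), HIST1H4H, HIST2H3C (2.17 to 50.1) and HIST1H2BN (4.62 to 86.9). The 15 lowest ratios included the immediate early gene IER3, at 509.8 FPKM in untreated and 8.04 in ACBP-S-Se cells (chromosome 6, 30743199 to 30744554, minus strand), PPP1R1B, which encodes the phosphatase inhibitor DARPP-32 (241 to 7.53), the cytochrome P450 gene CYP2B6 (29.3 to 0.341), the ciliary transcription factor FOXJ1 (112 to 5.52), the prion protein gene PRNP (45.9 to 1.86), SEMA3A (24.4 to 1.04), PRR15L (19.4 to 0.361) and C4orf3 (13.7 to 0.0804). The histones HIST1H4K (213 to 1.23), HIST1H1E and HIST1H2BD (169 to 8.04) and the genes EEF1G (561 to 5.65), ATP5J2 (113 to 1.98) and COX8A (47.2 to 1.54) were also among them. Measured as aligned bases over every transcript of their loci, 24 of the 30 genes were past a fold of 2 in the same direction. HIST2H4B, HIST2H3C, HOXB7, EEF1G, ATP5J2 and COX8A were not, with locus log2 ratios of -0.10, -0.32, -0.081, -0.075, 0.15 and -0.92. In annotated isoforms alone HIST1H2BN had a log2 ratio of 0.41, CBX6 of 1.20, DNAH17 of 1.78, SEMA3A of -1.54 and CYP2B6 of -2.95, against 3.97, 3.62, 3.95, -3.64 and -4.50 over all isoforms. HIST1H4K had no annotated isoform. HIST2H2AA4 had a locus log2 ratio of 1.44 against 4.18.

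**Figure D3:**
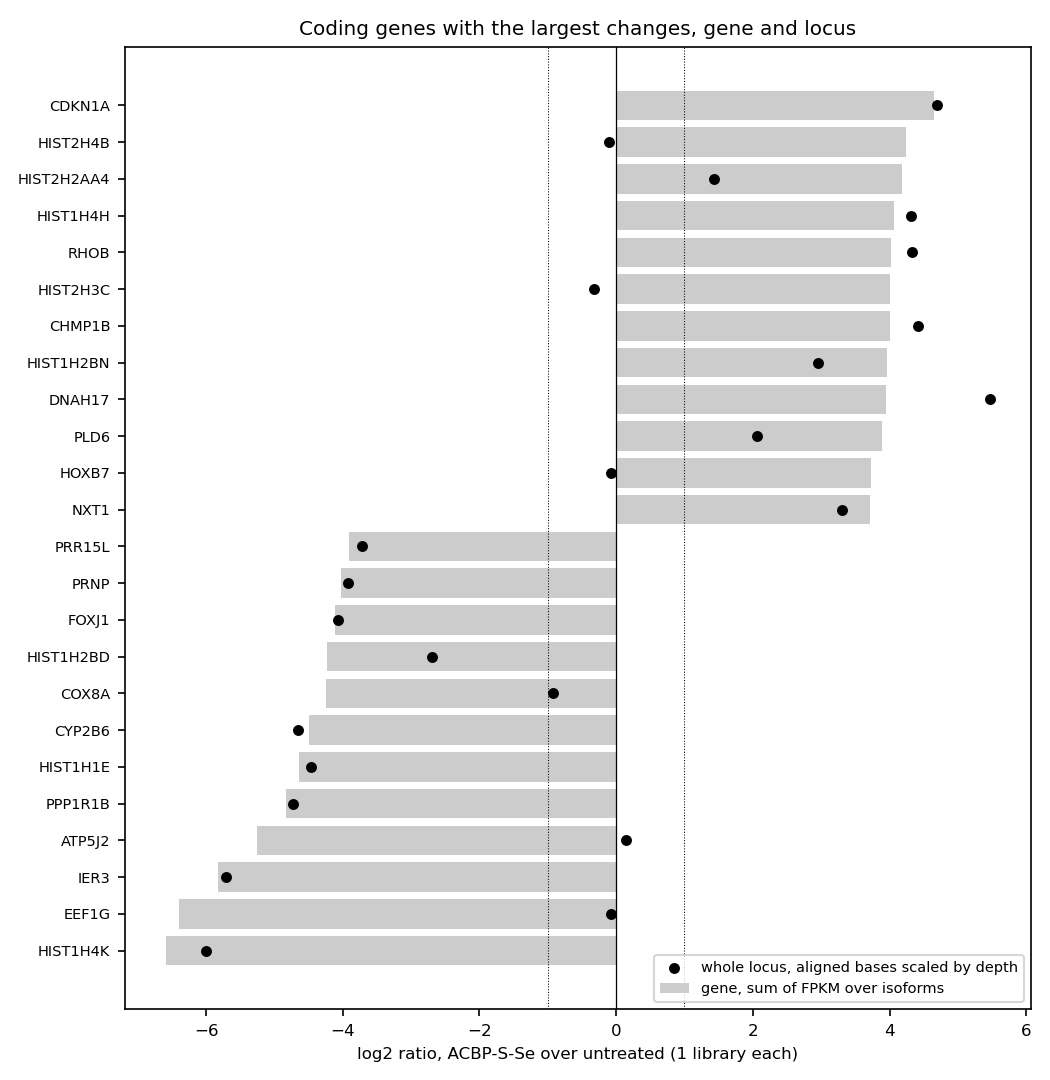
Log2 ratio of ACBP-S-Se over untreated for the 12 coding genes with the highest and the 12 with the lowest ratios, as the sum of FPKM over the gene's isoforms (bars, pseudocount 1) and as depth-scaled aligned bases over the whole locus (points, pseudocount 2), 1 library per group; dotted lines mark a fold of 2. CDKN1A lies at 4.64 and 4.70, and EEF1G at -6.40 and -0.075.

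Long noncoding RNAs, recognised by name, showed 45 of 426 genes at least 2-fold higher and 69 lower, with a median log2 ratio of -0.037. The highest ratios belonged to KRTAP5-AS1 (0.128 to 8.303 FPKM; chromosome 11, 1571353 to 1602234, plus strand), LINC00862 (0.063 to 7.66), MZF1-AS1 (1.12 to 13.9), LINC01564 (0.191 to 5.11) and LINC00431 (0.1299 to 4.06). LHFPL3-AS2 (23.8 to 0.22; chromosome 7, 104893992 to 104926645, minus strand), LINC01909 (7.85 to 0.624), LINC01091 (8.34 to 0.742) and LINC00941 (11.02 to 1.27) were among the lowest. In annotated isoforms alone KRTAP5-AS1 had a ratio of 0.074, LINC00862 of 0.66 and LINC01564 of 0.12, and LHFPL3-AS2, LINC01909 and LINC00941 of -1.39, -0.66 and -0.52, so most of the difference of these genes lay in assembled isoforms. Genes listed at 0 in a library and highest in the other were RNVU1-7 (13310.5 in untreated), RN7SL3 (2318 in untreated), RNU1-2 (8273 in ACBP-S-Se), HIST1H2AE (392 in ACBP-S-Se) and the mitochondrial rRNA gene MT-RNR2 (103 in ACBP-S-Se). These have near-identical copies or are abundant in every cell, so the zeros show only how they are listed. Small RNAs took 31% of summed FPKM in the untreated library and 21.2% in the ACBP-S-Se library.

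At the level of isoforms, 7693 of 32345 with a mean FPKM of at least 1 (23.8%) were at least 2-fold higher and 6209 (19.2%) lower. These shares were above those of genes. Among 400 genes that had 2 or more isoforms with a mean FPKM of at least 10 and a gene total that differed by less than 1.5-fold, 54 (13.5%) had isoforms that differed at least 4-fold in opposite directions. In the ribosomal protein gene RPS2, an assembled isoform was at 1602 FPKM in untreated and 64.6 in ACBP-S-Se cells, while the gene total was 1965 and 1748. RACK1, which encodes a ribosomal scaffold protein, had an assembled isoform listed at 0 and at 527 FPKM, with gene totals of 1053 and 757. Both genes were named after their values were seen.

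Ratios also varied with transcript length. Over 11622 protein-coding genes the median log2 ratio went from -0.33 for genes with a mean transcript length of up to 800 nt to 0.39 for those over 8000 nt, and Spearman's rho across genes, which are not independent replicates, was 0.154. With random lists matched on length as well as expression, 9 of the 10 lists outside the bounds stayed outside, replication-dependent histones being the exception.

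**Figure D4:**
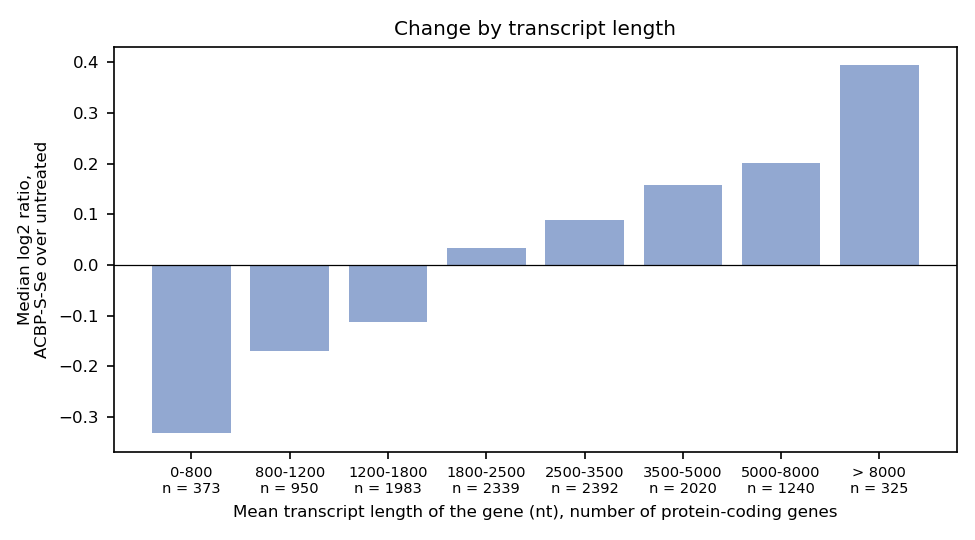
Median log2 ratio of ACBP-S-Se over untreated FPKM (y axis, pseudocount 1) for protein-coding genes in bins of mean transcript length in nt (x axis, number of genes under each bar), 1 library per group. The medians go from -0.33 in the shortest bin to 0.39 in the longest.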

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

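Tests chosen only after their result was seen were the comparison of list medians for scaling, the overlapping transcripts of genes whose locus changed little, and the question of culture differences. The remaining tests were set before their result was seen, but the rule set for the histone sum was not used, as given below.

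Outside named genes, 1574 assembled transcripts have no gene name, 519 of them with a mean FPKM of at least 1. No comparison of genes above uses these 519 transcripts, but the isoform counts include them. Among them, 107 were at least 2-fold higher in ACBP-S-Se than in untreated cells and 121 were lower, with a median log2 ratio of -0.00251.

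The first pattern is that the CDKN1A, MDM2 and BBC3 group was higher while the replication and mitosis lists were lower. A transcript length trend is argued against, since with length matching the CDKN1A, MDM2 and BBC3 group stayed at percentile 100 and the replication and mitosis lists at 0.01 and 0. Isoform assignment is also argued against, as 15 of 15 genes of that group that were at least 2-fold higher stayed so over whole loci, and 13 of 15 lower replication and mitosis genes did. Scaling moves all genes alike, and the group's and the mitosis medians differed by 2.12 log2 units. A response to ACBP-S-Se and a difference in culture or handling between the dishes, such as density, cannot be told apart, because there was 1 library per group.

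The second pattern is the size of the largest single-gene changes. Isoform assignment as the whole cause is argued against by the 24 of 30 coding genes that stayed past a fold of 2 over whole loci. For the other genes it stays open, since 3 of 6 had an overlapping transcript of another name that went the other way. For EEF1G this was a read-through isoform that joins it to a neighbouring gene, listed at 0 in untreated and 307 FPKM in ACBP-S-Se cells. A second assembled read-through isoform there went the same way as EEF1G, from 146 FPKM in untreated to 0.653 in ACBP-S-Se cells. Reads shared between histone copies also stay open for the histones. Summed histone FPKM in ACBP-S-Se was 0.616 of that in untreated cells (7959 and 4900.3 over 53 genes). By the rule set beforehand, a change of the sum by more than 1.5-fold counted against sharing, and the sum passed that limit. The rule was not used, because the limit of 1.5-fold was wrong for a design with 1 library per group, since the sum has no spread to set against it. The sum also moved far less than each of the 5 higher and 3 lower histones among these 30 genes, so it does not exclude sharing as a cause of their changes.

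The third pattern is the lower antioxidant enzyme list. Its members are short transcripts, of which genes in general were lower, yet with length matching it lay at percentile 0.51, and over whole loci at 0.06, which argues against the length trend and isoform assignment as the whole cause. With each gene read from its highest isoform it came within the bounds, at percentile 5 with a median of -0.42, so the size of the difference depends on how isoforms are read. The difference between treatment and culture stays open here too.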

How the results depend on the processing

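Alternatives added after the data were seen were whole loci, the removal of intronic, antisense and flanking transcripts, length matching and leaving out genes listed at 0 in a library. The lists of the CDKN1A, MDM2 and BBC3 group, hypoxia and glycolysis, DNA replication, mitosis and gastric and intestinal epithelium kept their call in all 12 alternatives. Of 115 named genes with values above 0 in both libraries, 83 kept their sign and their side of a fold of 2 in all 11 alternatives run for genes.

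Counts moved by over 1.5 times with a mean of at least 5, where fewer features were tested: 1095 genes higher and 957 lower, and 2093 isoforms higher and 2011 lower. Without a filter, 9342 isoforms were lower, as more were tested.

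Lists that came within the bounds lay at these percentiles: with a mean of at least 5 autophagy and lysosome 96.96, with the highest isoform antioxidant enzymes 5, selenoproteins 71.4, interferon response 6.17 and autophagy and lysosome 97.1, with annotated isoforms interferon response 8.69 and autophagy and lysosome 93.8, with whole loci selenoproteins 94.8 and interferon response 3.97, with genes listed at 0 left out selenoproteins 96.7, and with length matching replication-dependent histones 3.38. Lists that went outside the bounds lay at these percentiles: with a pseudocount of 0.1 NRF2 targets 97.8, with no filter nuclear-encoded respiratory chain 2.44, with a mean of at least 5 immediate early genes 98.3, and with centring fatty acid synthesis 2.49. More such lists were found: with trimmed-mean scaling fatty acid synthesis 2.4, with the highest isoform fatty acid synthesis 0.36, nuclear-encoded respiratory chain 1.72 and snoRNA host genes 99.5, with annotated isoforms NRF2 targets 99.8, metallothioneins and zinc transport 2.15, apoptosis pathway 97.7, fatty acid synthesis 0.73, nuclear-encoded respiratory chain 0.93 and immediate early genes 99.6, with whole loci fatty acid synthesis 1.93 and cytosolic ribosomal proteins 0.5, with intronic, antisense and flanking transcripts removed nuclear-encoded respiratory chain 2.04, and with length matching fatty acid synthesis 1.2 and snoRNA host genes 99.3. Named genes whose sign reversed had log2 ratios as follows: with the highest isoform MGST1 0.044, ABCC3 0.11, SLC39A10 1.53, with annotated isoforms SQSTM1 -2.01, and with whole loci HIST2H4B -0.10, HIST2H3C -0.32, HOXB7 -0.081, ATP5J2 0.15. For these lists and genes the cause was not tested. Trimmed-mean scaling gave 1608 genes higher and 1767 lower, and no scaling alternative moved the median of all genes by over 0.1. No limma fit, replicate block, left-out column or count model was run, since there was 1 column of values per group and no counts. Depth in reads is unknown, so differences of low genes cannot be set against counting error.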

Other observations

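Pathways named in the deposited table were examined only after the lists above had been seen, and their genes were chosen after their values were seen. Genes of the circadian rhythm had a high median (median log2 ratio 0.77 over 28 genes, percentile 100, 99.99 with length matching), 10 of them being at least 2-fold higher and 1 lower. The clock repressor BHLHE41 stood at 1.28 FPKM in untreated and 12.8 in ACBP-S-Se cells, the clock activator ARNTL at 3.75 and 13.6, PER1 at 10.1 and 29.1, CRY1 at 3.69 and 10.3, and NR1D1 at 6.57 and 15.4. The pathway of drug metabolism by cytochrome P450 had a low median (median log2 ratio -0.83 over 25 genes, percentile 0, 0 with length matching), 10 of its genes being at least 2-fold lower and 2 higher. CYP2B6 stood at 29.3 and 0.341 FPKM, the monoamine oxidase MAOB at 11.2 and 1.53, and the glucuronosyltransferase UGT1A6 at 42.5 and 8.11. Over its whole locus, UGT1A6 had a log2 ratio of -1.03 in place of -2.25. Genes that this pathway shares with the antioxidant enzyme list include MGST2, GSTO1 and GSTK1, so the low medians are not independent.

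Glycine, serine and threonine metabolism also had a low median (median log2 ratio -0.70 over 30 genes, percentile 0.01, 0 with length matching), 10 genes being at least 2-fold lower and 4 higher. The serine synthesis enzymes PHGDH (118 to 48.01 FPKM), PSAT1 (73.7 to 23.5) and PSPH (54.4 to 21.1) and the mitochondrial hydroxymethyltransferase SHMT2 (199 to 88.2) were each at least 2-fold lower. These are members of the ATF4 stress response list, in which ATF4 itself was at 379.7 and 578 FPKM and the amino acid transporter subunit SLC3A2 at 118 and 389, so that list held groups of genes that went opposite ways. Mismatch repair had a low median (median log2 ratio -0.55 over 22 genes, percentile 0.17, 0.18 with length matching), although only 6 genes were at least 2-fold lower and 0 higher. MSH3 was at 16.04 and 4.101 FPKM. The pathway also holds LIG1 (10.4 to 3.26 FPKM), a member of the DNA replication list, so it is not independent of that list. Mucin-type glycosylation genes also had a low median (median log2 ratio -0.61 over 19 genes, percentile 0.275, 0.13 with length matching), 7 being at least 2-fold lower and 1 higher. Among them GCNT3 was at 33.9 and 6.996 FPKM and GALNT10 at 40.8 and 9.52. Over its whole locus, GALNT10 had a log2 ratio of -1.23 in place of -1.99. Of 268 pathways with 15 to 200 tested genes, 14 lay above and 34 below the bounds under both matchings, where chance would place 13.4 outside under either; pathways share genes and are not independent.

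Immediate early genes went both ways. IER3 (509.8 to 8.04 FPKM), ZFP36 (13.01 to 0.199) and FOS (46.9 to 16.3) were lower, while JUN (32.01 to 111), ATF3 (14.99 to 55.8) and MYC (3.25 to 9.63) were higher, and JUNB was listed at 0, which may be a failed estimate, and at 34.4. In the apoptosis pathway list, 5 of 24 tested members were at least 2-fold higher and 1 lower. The lower member, named after its value was seen, was the anti-apoptotic gene BCL2L1 (31.3 FPKM in untreated and 6.08 in ACBP-S-Se cells). MDM2 was at 64.6 and 159 FPKM.

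Among unnamed transcripts with a mean FPKM of at least 5, a single-exon transcript on chromosome 16 (57299950 to 57300274, plus strand) was at 23.6 FPKM in untreated cells and listed at 0 in ACBP-S-Se cells. Another on chromosome X (119606071 to 119606421, minus strand) was at 16.6 and listed at 0. The highest log2 ratio at this mean was 0.85 (19.5 to 36.0 FPKM, on chromosome 17), so none of these transcripts was 2-fold higher.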
